A study of Homo sapiens with 15 samples.

How the data were processed

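The samples were H9 cells, an established human embryonic stem cell line, differentiated toward the osteogenic lineage and collected on day 7. Per the labels, cultures spent the days up to day 5 in serum medium that lets cells differentiate on their own, and received vitamin D3, β-glycerophosphate and ascorbic acid from day 5. Particles were present from day 0. The 15 libraries fall into 5 groups of 3: a vehicle control that received DMSO at 0.1% (UNT), fine particulate matter (FPM) at 0.00062 and 1.4 µg/mL, and a NIST standard reference material (SRM) at 0.003 and 5.9 µg/mL. The labels call these concentrations the IC25 and IC50 of each particle and base them on protein. Within a particle the IC50 was 2258 times (FPM) or 1967 times (SRM) the IC25. Polyadenylated RNA was prepared with a directional library kit, per the labels' protocols, so that reads should keep the strand of the transcript they came from.

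The deposited table holds whole-number read counts per gene. Per the submitters' processing notes, the authors aligned reads to GRCh38 with HISAT2 2.2.1, handled the alignments with SAMtools 1.10, counted with featureCounts from Subread 2.0.15, checked reads with FastQC 0.11.7 and used DESeq2. The annotation release, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. A second deposited table holds FPKM values, which the authors derived from the same counts, as their ratio to the counts shows. The columns of the control are named differently from the titles, and were matched through the descriptions; 1 column, the gene length, belongs to no sample. Genes that share reads with near-identical copies, and genes that overlap another gene, are uncertain, because the counting of such reads is not described.

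The files list 60675 genes by Ensembl identifier. Coordinates (1-based, GRCh38) and gene types came from GENCODE release 29, on which 57055 were placed. Symbols came from a separate list of gene names, with the GENCODE name where that list had none, and 41706 had an approved symbol. Each gene was put into a class by what lies on the other strand: exons overlapping exons of an opposite gene, a position within an opposite gene's body, an opposite gene within 5 kb, or none of these. Of the 19012 genes tested, 8144, 3140, 3331 and 4239 fell into these classes in that order, and 158 were not placed. GC content was that of each gene's longest transcript.

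Total counts ranged from 9.34 to 58.2 M (M, mega) per library. A floor of 3 counts corresponded to 0.0515 to 0.321 CPM (counts scaled by library size) in a library. PCR reads without molecular identifiers are not independent molecules, so floors cover counting error only. Replicate pairs had Pearson correlations of log2 CPM between 0.982 and 0.994, and each pair differed by more than sampling noise (chi-square per gene of at least 5.50), so all libraries were counted. The labels do not say that replicates were separate cultures; all p-values therefore measure only the spread between these samples, which may be technical.

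Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr, robust quasi-likelihood fits of the 5 group means to all 15 libraries, and an F test per contrast with Benjamini-Hochberg adjustment at 0.05. Every adjusted p of a gene is from this test unless another tool is named. CPM values are TMM-scaled and given as mean ± SD over 3 libraries; log2 fold changes carry a standard error (SE). Each exposure was set against UNT, the doses of a particle against each other, and the particles against each other at the same inhibitory level; 1 F test covered all 5 groups. Fixed gene lists (45, of which 44 had at least 4 measured members) were tested with camera in limma 3.58.1, with a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. Members were also adjusted over the list alone.

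Named genes follow a rule. Against UNT it takes the 8 higher and 8 lower genes with the largest fold among those with adjusted p under 0.05, a mean of at least 1 CPM over the 6 libraries, no overlap between the groups and an approved symbol of a gene that is not a clone, antisense transcript or, by its GENCODE type, a pseudogene. BCRP3 and TEX56P, pseudogenes by name, have other types there and were kept. Chance gives groups that do not overlap in 10% of genes for 3 against 3. Between doses or particles it takes 5 each way. Up to 4 called members per list, and 12 markers of exposure and lineage whatever their p, are added. The design, the rule, the lists and most alternatives were fixed before the data were examined; the class of opposite-strand genes, the GC correction and the fit without FPM libraries were added after seeing the data.

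Alternatives were DESeq2 1.42.0, its size factors within edgeR, no expression filter, the replicate number as a block, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) with FPKM of at least 1 in 3 libraries, only the 6 libraries compared, and each replicate left out in turn. Added were tests on genes with no opposite-strand gene within 5 kb, a per-library lowess offset on GC content (span 0.5), both together, and the 9 UNT and SRM libraries alone. Replicate numbers were taken as pairing only where all 3 correlations of same-numbered deviations from group means exceeded 0.1. This held for FPM_IC50 against FPM_IC25 (0.18, 0.21 and 0.26), by this check and not by a label. The main results for that comparison still come from the fit without the block. By the same deviations, 11 of 15 libraries were closest to a same-numbered library of another group. Replicate numbers may thus carry structure in other comparisons too. The test was run on simulated counts for 17253 genes. At log2 changes of 0.5, 1 and 2 in size it recovered 24.6%, 80.3% and 94.9% of changed genes for SRM_IC50 against UNT. Figures were drawn with matplotlib.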

Results

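Gene-level read counts were measured in 15 libraries of differentiating H9 human embryonic stem cells collected on day 7, in 5 groups of 3. Total counts were 17.3 to 20.1 M (M, mega) in the vehicle controls (UNT), 9.34 to 58.2 M at FPM_IC25, 9.77 to 19.5 M at FPM_IC50, 13.2 to 51.2 M at SRM_IC25 and 12.04 to 29.2 M at SRM_IC50. Between 15713 and 21682 genes had at least 10 counts in a library. The series asks how the particles alter early osteogenic differentiation. The FPM libraries stood apart in the share of counts in antisense genes. Genes annotated as antisense took 1.07% ± 0.173 (SD, n = 3) of counts at FPM_IC25 and 1.21% ± 0.252 at FPM_IC50, against 0.282% ± 0.00768 in UNT, 0.2998% ± 0.00311 at SRM_IC25 and 0.303% ± 0.0156 at SRM_IC50. The leading principal component of log2 CPM held 75.9% of the variance over all tested genes, where it set the 6 FPM libraries apart. Over genes with no opposite-strand gene within 5 kb it held 44.0% and set the 3 SRM_IC50 libraries apart.

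At SRM_IC50 against UNT, genes of amnion and trophoblast were far lower and genes of the pluripotent state were higher. CGA, which encodes the alpha subunit of chorionic gonadotropin (ENSG00000135346, GRCh38 chromosome 6, 87085498 to 87095406), was 0.820 ± 0.132 CPM at SRM_IC50 and 44.5 ± 11.6 CPM in UNT (SD, n = 3). Its log2 fold change was -5.79 (SE 0.34, adjusted p = 1.48e-08). CYP19A1, the aromatase that makes oestrogens, fell from 21.1 ± 2.19 to 0.709 CPM, and the envelope genes ERVW-1 (log2 -6.04) and ERVFRD-1 (-5.88), which encode the fusogenic syncytins, fell to 0.0812 and 0.0689 CPM, near the counting floor. GCM1, the transcription factor that drives trophoblast fusion, fell by 5.60 on the log2 scale, and PRR9 (-5.64), LGALS16 (-5.20), a placental galectin, and the receptor gene MRGPRX1 (-5.18) completed the 8 largest falls. The amnion and trophoblast list had 20 of 21 measured members lower and 1 higher, and the same numbers adjusted over the list alone. Its median log2 fold change was -2.61 (camera adjusted p = 2.84e-63, and adjusted p = 0.00329 with an estimated correlation). GABRP, an amnion marker, was -2.57 and GATA2, a trophoblast regulator, was -2.61 on the log2 scale.

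The pluripotency list had 13 of 21 members higher and 1 lower at SRM_IC50, and 15 higher and 1 lower adjusted over the list alone. Its median was 1.00 (adjusted p = 4.17e-18, and adjusted p = 0.00116 with an estimated correlation). NANOG, a core pluripotency factor (chromosome 12, 7787794 to 7799141), rose from 5.95 ± 1.06 to 18.5 ± 2.11 CPM, a log2 fold change of 1.64 (SE 0.16, adjusted p = 2.66e-06). PRDM14, a repressor of differentiation genes, rose from 3.44 ± 0.815 to 22.9 ± 2.93 CPM (log2 2.73), POU5F1 by 1.42, SOX2 by 1.00 and TDGF1, a Nodal co-receptor, by 2.49. Other genes with the largest rises were HES3 (3.52), LCK (3.08), the retinol esterifying enzyme LRAT (2.85), SNCB (2.72), NPR1 (2.62), UTF1 (2.60), an embryonic stem cell transcription factor, and UNC13A, which rose from 2.19 ± 0.558 to 12.4 ± 3.30 CPM. FGF and ERK targets had 10 of 22 members higher and none lower, and 12 higher and 1 lower adjusted over the list alone. Their median was 0.42 (adjusted p = 5.02e-06, and adjusted p = 0.0119 with an estimated correlation), with ETV4 at 1.27, FGF2 at 0.86 and DUSP6 at 0.73.

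Markers of epithelium and of lateral plate mesoderm fell at SRM_IC50. The simple epithelium list had 17 of 18 members lower, also adjusted over the list alone, with a median of -0.88 (adjusted p = 1.34e-24, and adjusted p = 0.0276 with an estimated correlation). The keratin gene KRT7 went from 216 ± 43.7 to 33.5 ± 3.89 CPM, GRHL2, a regulator of epithelial identity, fell by 1.58 on the log2 scale and the tight junction gene CLDN4 by 1.34. Lateral plate and cardiac mesoderm genes had 9 of 17 members lower, also adjusted over the list alone, with a median of -0.66 (adjusted p = 5.02e-06, but adjusted p = 0.189 with an estimated correlation). HAND1, a transcription factor of that lineage and of extraembryonic tissue, fell from 211 ± 28.7 to 34.4 ± 7.53 CPM, GATA6 fell by 1.97 and BMP4 by 0.66. The paraxial mesoderm list, with 7 of 17 lower and 3 higher, did not pass (adjusted p = 0.0999). Imprinted growth genes had 5 of 14 lower and 1 higher, and 7 lower and 2 higher adjusted over the list alone, with a median of -0.19 (adjusted p = 0.00210, and adjusted p = 0.0462 with an estimated correlation). H19 was -2.17, IGF2, a growth factor, was -2.06 and CDKN1C, a cell cycle inhibitor, was -1.59.

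Genes of the intended bone lineage went both ways at SRM_IC50. The osteoblast lineage list had 4 of 17 members higher and 4 lower, and 5 each way adjusted over the list alone; its median was 0.03, its mean -0.01 and its test pointed down (adjusted p = 0.795). ALPL, an alkaline phosphatase found in mineralising cells (chromosome 1, 21509372 to 21578412), rose from 88.3 ± 7.59 to 162 ± 6.25 CPM, a log2 fold change of 0.87 (SE 0.088, adjusted p = 2.84e-06). ALPL rose together with NANOG (1.64), POU5F1 (1.42) and SOX2 (1.00), so its rise need not reflect the bone lineage. COL1A1, the main bone collagen gene, rose by 0.61, whereas the homeobox genes DLX3 (-1.15), DLX5 (-1.14) and MSX2 (-0.70) fell. RUNX2 (-0.54, adjusted p = 0.0946), SP7 (0.91, adjusted p = 0.0514) and SPP1 (0.34, adjusted p = 0.218) did not pass the test. Collagens and matrix genes had 11 of 33 lower and 5 higher, and 11 lower and 6 higher adjusted over the list alone, with a median of -0.13 (adjusted p = 0.00210, but adjusted p = 0.598 with an estimated correlation). LUM (-2.70) and DCN (-2.15), which encode small matrix proteoglycans, and COL3A1 (-1.36) were among those that fell. COL1A1 no longer passed without UNT replicate 3 (adjusted p = 0.0633) or SRM_IC50 replicate 1 (adjusted p = 0.0852), nor the matrix list without SRM_IC50 replicate 3 (adjusted p = 0.0541).

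Among markers of exposure at SRM_IC50, CYP1A1, an enzyme induced by aryl hydrocarbon receptor ligands, rose from 6.53 ± 0.662 to 13.4 ± 2.48 CPM, a log2 fold change of 1.06 (SE 0.18, adjusted p = 0.000578). CYP1B1 rose by 0.62 and CYP2S1 by 1.34, while AHR, the receptor, fell by 0.60. The list of its targets had 3 of 8 higher and 1 lower, also adjusted over the list alone, and did not pass its test (adjusted p = 0.0934). HMOX1 (-0.10, adjusted p = 0.735) and NQO1 (0.19, adjusted p = 0.471), which respond to oxidative stress, did not pass, nor did the NRF2 target list, with 3 of 21 higher and 1 lower, also adjusted over the list alone (adjusted p = 0.382). In all, 1513 genes were higher and 1824 lower at SRM_IC50, of which 443 and 672 differed by more than 2-fold. Exons of CYP19A1, KRT7, POU5F1, TDGF1, CYP1B1, H19, IGF2, ETV4, FGF2 and DUSP6 overlap exons of an opposite gene, so their values are uncertain. Over genes with no opposite-strand gene within 5 kb, 1058 of 4239 were called, and the FGF and ERK list (adjusted p = 0.311) and the imprinted growth list (adjusted p = 0.473) no longer passed. Of 158 named genes called at SRM_IC50, 130 kept their call with each library left out in turn.

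**Figure D1:**
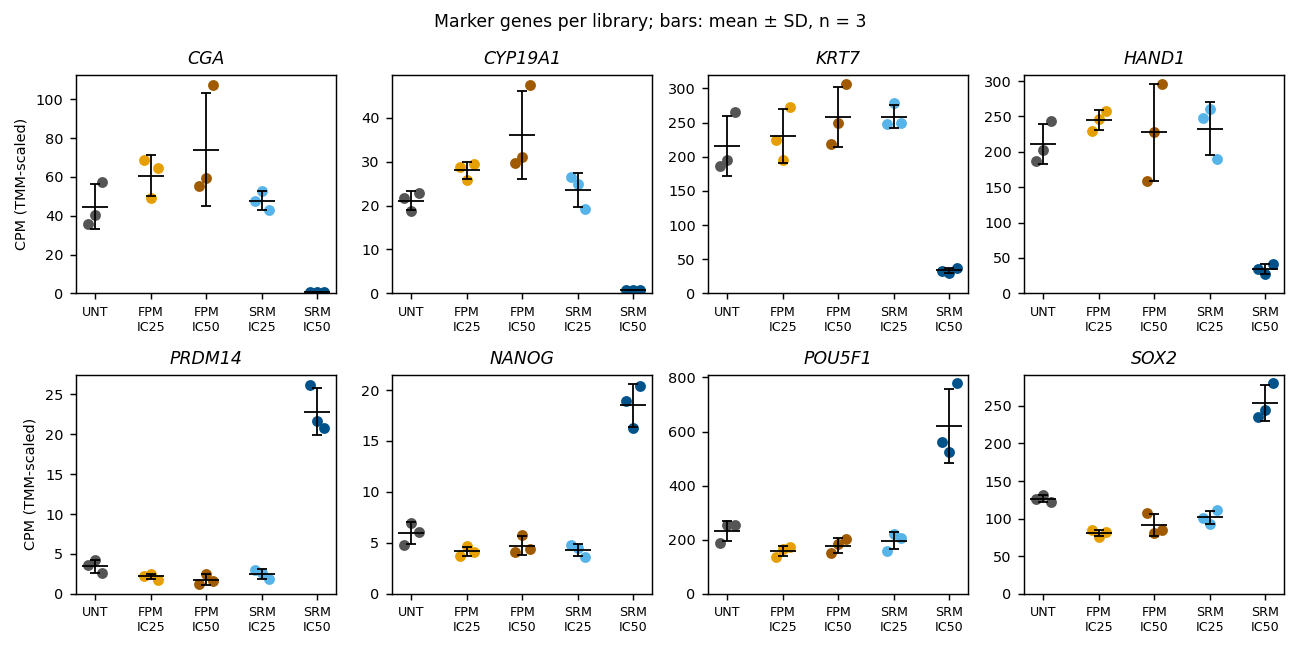
Normalised expression (CPM, linear axes from 0) of CGA, CYP19A1, KRT7, HAND1, PRDM14, NANOG, POU5F1 and SOX2 in each library of the 5 groups, with bars for the mean and SD of 3 libraries. At SRM_IC50, CGA lay at 0.820 ± 0.132 CPM against 44.5 ± 11.6 in UNT, and NANOG at 18.5 ± 2.11 against 5.95 ± 1.06.

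At SRM_IC25 against UNT, changes were small, and the genes called followed GC content. The pluripotency list had 4 of 21 members lower, and 6 lower adjusted over the list alone, with a median of -0.26 (adjusted p = 0.000498, but adjusted p = 0.273 with an estimated correlation). It did not pass over genes with no opposite-strand gene within 5 kb (adjusted p = 0.101), but passed after a correction for GC content (adjusted p = 1.055e-11; list: pluripotency, SRM_IC25_vs_UNT). LIN28A, an RNA-binding protein of stem cells, fell by 0.51 on the log2 scale (SE 0.10, adjusted p = 0.0226), TDGF1 by 0.59, L1TD1 by 0.60 and DPPA4 by 0.31. The neural crest list had no called member of 22 by edgeR, over all genes or adjusted over the list alone, with a median of 0.17 (adjusted p = 0.0423, but adjusted p = 0.971 with an estimated correlation). It did not pass without UNT replicate 2 (adjusted p = 0.0976), UNT replicate 3 (adjusted p = 0.0617) or SRM_IC25 replicate 3 (adjusted p = 0.199), nor after a correction for GC content. With that correction, 6 lists passed that had not: neuroectoderm (adjusted p = 1.76e-05), heat shock (adjusted p = 0.000343), aryl hydrocarbon receptor targets (adjusted p = 0.01345), FGF and ERK targets (adjusted p = 0.01345) and cell cycle (adjusted p = 0.0347) downward, and replication-dependent histones (adjusted p = 0.00774) upward. Cholesterol synthesis genes had 4 of 23 lower, and 8 lower and 1 higher adjusted over the list alone; the median was 0.01, the mean -0.04 and the test pointed down (adjusted p = 0.385). The largest rises were in SNORD3A (2.25), BEST1 (2.09), GPS2 (1.60), BCRP3 (1.48), SPTBN5 (1.08), PNPLA7 (1.05), ZNF460 (1.00) and ISM2 (0.75). Exons of BEST1, GPS2, BCRP3, SPTBN5 and ZNF460 overlap exons of an opposite gene, as do those of 100 of the 188 genes called higher (53.2%), so these values are uncertain. How the selection of polyadenylated RNA treated SNORD3A and the replication-dependent histones is not known here, so their values are uncertain too. The largest falls were in NOS1 (-1.16), TTC23L (-1.07), MNS1 (-1.04), ANKRD12 (-0.98), CCDC152 (-0.96), KIF20B (-0.96), ESF1 (-0.94) and MT-TQ (-0.92).

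None of the 12 exposure and lineage markers was called at SRM_IC25 (edgeR). The log2 fold changes were -0.13 for CYP1A1, -0.40 for CYP1B1, 0.13 for HMOX1, -0.15 for NQO1, 0.19 for RUNX2, 0.26 for SP7 and 0.02 for ALPL. They were 0.30 for COL1A1, -0.39 for SPP1, -0.24 for POU5F1, -0.46 for NANOG and -0.32 for SOX2 (smallest adjusted p = 0.0945, SOX2). Of 831 called genes, 188 were higher, with a median GC content of 60.8%, and 643 lower, with a median of 38.7%, against 48.9% in genes not called. Across genes, which are not independent replicates, log2 fold change and GC content had a Spearman correlation of 0.57. With a GC correction, chosen after seeing the data, edgeR called 0 genes (1304 at unadjusted p under 0.05). The count (genes changed: SRM_IC25 vs UNT) was also 0 in edgeR fits without UNT replicate 2, SRM_IC25 replicate 2 or SRM_IC25 replicate 3, 2 without UNT replicate 3 and 319 without SRM_IC25 replicate 1, while DESeq2 called 1976. None of the 44 named genes called at SRM_IC25 kept its edgeR call in every fit that left out 1 library.

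**Figure D2:**
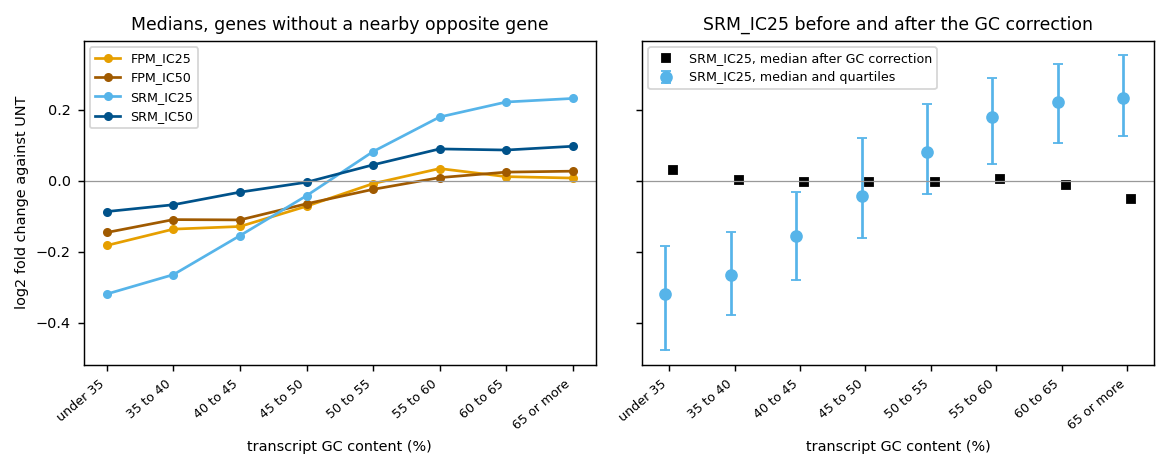
Log2 fold change against UNT (vertical axis) of genes with no opposite-strand gene within 5 kb, in bins of transcript GC content (percent, horizontal axis), as medians for each exposure (left) and for SRM_IC25 as medians with quartiles before and medians after the GC correction (right). At SRM_IC25, genes called higher had a median GC content of 60.8% and genes called lower 38.7%.

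Between the SRM doses, pluripotency genes were higher and genes of amnion, trophoblast and simple epithelium lower at SRM_IC50. The neural crest (adjusted p = 0.608) and neuron (adjusted p = 0.0539) lists did not pass between the doses. At SRM_IC50 the pluripotency list had 17 of 21 members higher and 1 lower than at SRM_IC25, also adjusted over the list alone, with a median of 1.26 (adjusted p = 5.42e-23, and adjusted p = 0.000642 with an estimated correlation). NANOG was higher by 2.10 on the log2 scale (SE 0.17, adjusted p = 1.84e-07), TDGF1 by 3.08, PRDM14 by 3.21, LRAT by 3.48, LCK by 3.48 and HES3 by 3.18. The amnion and trophoblast list had 20 of 21 lower and 1 higher, also adjusted over the list alone, with a median of -2.74 (adjusted p = 1.27e-52, and adjusted p = 0.00747 with an estimated correlation). CGA differed by -5.90, ERVW-1 by -6.42 and ERVFRD-1 by -6.09. Simple epithelium genes had 16 of 18 lower, and 17 adjusted over the list alone (adjusted p = 1.19e-22, and adjusted p = 0.0408 with an estimated correlation). Aryl hydrocarbon receptor targets had 3 of 8 higher, and 4 adjusted over the list alone, with a median of 0.35 (adjusted p = 0.00557, but adjusted p = 0.283 with an estimated correlation). CYP1A1 was higher by 1.19, CYP1B1 by 1.02, CYP2S1 by 1.21 and ALPL by 0.86. In all, 2605 genes were higher and 2510 lower at SRM_IC50 than at SRM_IC25. With the genes limited to those with no opposite-strand gene within 5 kb, 691 were higher and 687 lower.

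At FPM_IC25 against UNT, the neuroectoderm and pluripotency lists were lower, and a few genes of mesenchyme were higher. SIX3, an eye field transcription factor, fell from 26.2 ± 2.27 to 11.2 ± 4.40 CPM, a log2 fold change of -1.24 (SE 0.23, adjusted p = 0.00100). The eye field genes RAX (-1.48) and SIX6 (-1.36), the melanin enzyme gene DCT (-1.93), and CPLX4 (-1.89), BHMT (-1.37) and F2RL2 (-1.27) were among the largest falls. These falls were not particular to FPM_IC25, as each of these genes was also lower at SRM_IC50 than in every UNT library. There RAX lay at 8.848, 5.853 and 5.627 CPM and SIX3 at 10.78, 10.48 and 11.61. The neuroectoderm list at SRM_IC50 passed only over genes with no opposite-strand gene within 5 kb, and upward (camera adjusted p = 0.0259). The neuroectoderm list had 10 of 22 members lower, and 11 adjusted over the list alone, with a median of -0.47 (adjusted p = 0.000761, but adjusted p = 0.873 with an estimated correlation). FPM_IC25 replicate 2 lay lowest, with RAX at 5.94 CPM against 19.45 and 18.72 in the other FPM_IC25 libraries and SIX3 at 6.08 against 13.89 and 13.51; the list (list: neuroectoderm, FPM_IC25_vs_UNT) also passed without it (adjusted p = 0.00219). The pluripotency list had 6 of 21 lower, and 9 adjusted over the list alone, with a median of -0.32 (adjusted p = 0.00300, but adjusted p = 0.497 with an estimated correlation). LIN28A was -0.56, TDGF1, whose exons overlap exons of an opposite gene so that its value is uncertain, -0.59 and SOX2, which is also in the neuroectoderm list, -0.65. Both lists also passed over genes with no opposite-strand gene within 5 kb, with adjusted p = 0.000274 for 10 neuroectoderm genes and 2.9e-05 for 11 pluripotency genes. Mesenchymal transition genes had 6 of 15 higher, and 6 higher and 1 lower adjusted over the list alone; the list did not pass over all genes (adjusted p = 0.618), but its 5 members with no opposite-strand gene within 5 kb did, upward (adjusted p = 5.53e-07). With that restriction the collagens and matrix (adjusted p = 0.0170), neural crest (adjusted p = 0.0253) and amnion and trophoblast (adjusted p = 0.0171) lists also passed upward, having failed over all genes. PRRX1, a limb and craniofacial mesenchyme factor, rose by 0.68, SNAI1 by 0.61, PDGFRB by 0.48 and PDGFRA by 0.41. Ribosomal protein genes had a median of -0.26, and no called member of 34 by edgeR, over all genes or adjusted over the list alone (adjusted p = 0.0197, but adjusted p = 0.873 with an estimated correlation). That list did not pass without UNT replicate 3 (adjusted p = 0.185) or FPM_IC25 replicate 2 (adjusted p = 0.0814), nor over genes with no opposite-strand gene within 5 kb (adjusted p = 0.275).

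Among the 12 markers at FPM_IC25, ALPL fell from 88.3 ± 7.59 to 68.3 ± 5.03 CPM, a log2 fold change of -0.37 (SE 0.088, adjusted p = 0.00727). POU5F1 (-0.55, adjusted p = 0.0420) and SOX2 also passed, both lower, so the fall of ALPL need not reflect the bone lineage. Exons of POU5F1 overlap exons of an opposite gene, so its value is uncertain. POU5F1 did not pass without UNT replicate 2 or 3, or without FPM_IC25 replicate 1, 2 or 3 (adjusted p between 0.0535 and 0.183), nor after the GC correction (adjusted p = 0.06005). CYP1A1 (0.25), CYP1B1 (-0.27), HMOX1 (0.07), NQO1 (-0.21), RUNX2 (0.40), SP7 (-0.02), COL1A1 (0.30), SPP1 (-0.43) and NANOG (-0.50) did not. Mitochondrially encoded genes had 5 of 13 members lower and 1 higher, and 6 lower and 1 higher adjusted over the list alone (adjusted p = 0.123). MT-ND6, which lies on the other strand of the mitochondrial genome from most of its genes, was higher by 1.57, whereas MT-CO2 was -0.61 and MT-ATP8 -0.75. It lay at 315.7 to 343.2 CPM at FPM_IC25 and 348.6 to 426.5 at FPM_IC50. The UNT libraries had 99.71 to 130.6 CPM of MT-ND6 and the SRM libraries 65.46 to 123.5. As genes over opposite exons also rose in the FPM libraries only, the value of MT-ND6 is uncertain.

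The genes with the largest rises at FPM_IC25 all have exons that overlap exons of a gene on the opposite strand, so their values are uncertain. BEST1 (chromosome 11, 61949821 to 61965515, plus strand), a chloride channel gene, was 367 ± 70.0 CPM against 1.74 ± 0.602 in UNT, a log2 fold change of 7.71 (SE 0.38, adjusted p = 8.61e-10). It overlaps 1267 exon bases of the ferritin gene FTH1 (61959718 to 61967660, minus strand), which stood at 1608 CPM in UNT and differed by -0.34 (adjusted p = 0.260). TEX56P and PKD2L2 had 0 counts in all controls and were at least 140-fold and at least 76.5-fold higher, against a floor of 3 counts over the group. The others were KMO, FAM166A, PP2D1, CXCR5 and PMCH, which had 1 to 3 counts over all controls and lie opposite OPN3, TUBB4B, RAB5A, BCL9L and PARPBP. In all, 2025 genes were higher and 668 lower, and 90.2% of the higher genes overlap opposite exons. Of 1865 tested genes annotated as antisense, 1132 were higher at FPM_IC25 and 24 at SRM_IC25. Among genes with no opposite-strand gene within 5 kb, the fit over all genes called 54 higher and 172 lower. Fitted alone, 13 of those genes were higher and 17 lower, so calls at FPM_IC25 depend on which genes are tested together. Of 78 named genes called at FPM_IC25, 37 kept their call with each library left out in turn. With the replicate number as a block the count (genes changed: FPM_IC25 vs UNT) was 4079.

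**Figure D3:**
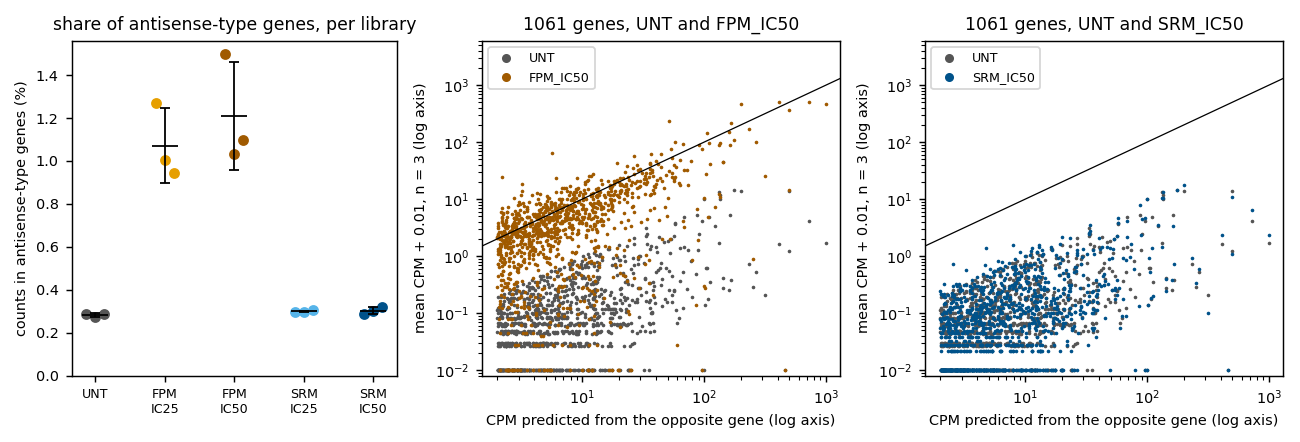
Share of counts in antisense genes (percent) in each library by group, and, for 1061 genes whose exons overlap an opposite gene, the mean CPM plus 0.01 observed (vertical) against the CPM predicted if the opposite gene's reads were also counted to them (horizontal), in UNT with FPM_IC50 and in UNT with SRM_IC50, on logarithmic axes with a line where both are equal. The 1061 genes were those with a prediction of at least 2 CPM and a UNT level under 10% of it, so UNT lies below the line by choice. The antisense share was 1.07% and 1.21% in the FPM groups and 0.282% in UNT.

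At FPM_IC50 against UNT, the genes that fell had smaller changes, and several amnion and trophoblast genes were higher. S100B, a calcium-binding protein of glia, fell by 1.06 on the log2 scale (SE 0.26, adjusted p = 0.0101), from 2.72 ± 0.222 to 1.31 ± 0.331 CPM. EFCC1 (from 2.29 to 1.07 CPM), the synaptotagmin SYT4 (-0.97), LHFPL4 (-0.96), the histone gene H2AC11 (-0.93), ANKRD18B (-0.92), the neurofilament gene NEFM (-0.91) and DNAJC12 (-0.90) followed. Among genes with no opposite-strand gene within 5 kb, the fit over all genes called 123 lower. Fitted alone, 0 of these were called lower by edgeR, so calls of falls depend on which genes are tested together. The amnion and trophoblast list had 4 of 21 members higher, and 5 adjusted over the list alone, but did not pass over all genes (adjusted p = 0.560); its 8 members with no opposite-strand gene within 5 kb passed upward (adjusted p = 0.0327). ERVW-1 rose by 0.99, CYP19A1 by 0.77, CGA by 0.73 and GATA2 by 0.45; the libraries of CGA and GATA2 overlapped between the groups. FPM_IC50 replicate 3 was highest in all 4 genes, with CGA at 107.4 CPM against 55.42 and 59.28 in the other FPM_IC50 libraries. Without it CGA in FPM_IC50_vs_UNT (adjusted p = 0.222), GATA2 in FPM_IC50_vs_UNT (adjusted p = 0.184) and ERVW-1 in FPM_IC50_vs_UNT (adjusted p = 0.0741) did not pass, and CYP19A1, which still did, overlaps opposite exons. Heat shock genes had 6 of 13 lower, and 8 adjusted over the list alone, with a median of -0.28 (adjusted p = 0.0330, but adjusted p = 0.844 with an estimated correlation), and the mitochondrial chaperonin HSPD1 fell by 0.46. Neural crest genes had 2 of 22 lower, and 1 adjusted over the list alone (adjusted p = 0.0443, but adjusted p = 0.844 with an estimated correlation), with DLX1 at -0.86. Cell cycle genes had 3 of 35 lower and 1 higher, and 6 lower and 1 higher adjusted over the list alone (adjusted p = 0.0282, but adjusted p = 0.844 with an estimated correlation). With the restriction to genes with no opposite-strand gene within 5 kb these 3 lists did not pass (adjusted p = 0.707 for heat shock, 0.148 for neural crest and 0.1096 for cell cycle), nor without FPM_IC50 replicate 2 (adjusted p = 0.0896 for heat shock, 0.0896 for neural crest and 0.0733 for cell cycle). Heat shock genes also did not pass without UNT replicate 3 (adjusted p = 0.0767) or FPM_IC50 replicate 1 (adjusted p = 0.0891), nor did neural crest genes without UNT replicate 1 (adjusted p = 0.116) or FPM_IC50 replicate 3 (adjusted p = 0.108).

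Of the 12 markers at FPM_IC50, SOX2 fell by 0.48 on the log2 scale (SE 0.11, adjusted p = 0.00494). The others did not pass: CYP1A1 (0.11), CYP1B1 (-0.08), HMOX1 (0.28), NQO1 (-0.28), RUNX2 (0.13), SP7 (-0.04), ALPL (-0.22), COL1A1 (0.10), SPP1 (-0.31), POU5F1 (-0.38) and NANOG (-0.30). Ribosomal protein genes had 1 of 34 members lower, RPL11, and 0 adjusted over the list alone (list adjusted p = 0.0156, but adjusted p = 0.866 with an estimated correlation). It did not pass without UNT replicate 3 (adjusted p = 0.0829) or FPM_IC50 replicate 2 (adjusted p = 0.0925), nor over genes with no opposite-strand gene within 5 kb (adjusted p = 0.148). The largest rises were in the same 8 genes as at FPM_IC25, each overlapping opposite exons. BEST1 was 453 ± 78.2 CPM, and TEX56P and PKD2L2 were at least 150-fold and at least 66.4-fold higher than a floor of 3 counts over the controls. In all, 2058 genes were higher, 90.5% of them over opposite exons, and 527 lower. Of these calls, 45 higher and 123 lower were genes with no opposite-strand gene within 5 kb. Fitted alone, 3 of those genes were higher and 0 lower by edgeR (596 either way at unadjusted p under 0.05). Of 63 named genes called at FPM_IC50, 27 kept their call with each library left out in turn.

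Between the FPM doses, genes of neural crest, neurons and mesenchyme were lower at FPM_IC50 than at FPM_IC25. DLX1, a homeobox gene of forebrain and branchial arches (chromosome 2, 172084740 to 172089677), was 4.39 ± 0.874 CPM at FPM_IC50 and 11.7 ± 4.03 at FPM_IC25, a log2 fold change of -1.41 (SE 0.21, adjusted p = 0.0411). FPM_IC25 replicate 2 lay highest (16.34 CPM, against 9.363 and 9.343), and without it the log2 fold change was -1.09 (adjusted p = 0.0387; DLX1 in FPM_IC50_vs_FPM_IC25). PRRX1 (chromosome 1, 170662728 to 170739419) was 7.53 ± 1.35 and 16.6 ± 3.61 CPM, a log2 fold change of -1.14 (SE 0.16, adjusted p = 0.0411). The neural crest list had 1 of 22 members lower, and 13 adjusted over the list alone, with a median of -0.46 (adjusted p = 8.93e-36, and adjusted p = 0.00285 with an estimated correlation). The neuron list had no called member of 18 over all genes by edgeR, and 8 lower adjusted over the list alone, with a median of -0.52 (adjusted p = 5.57e-15, and adjusted p = 0.00715 with an estimated correlation). Mesenchymal transition genes had 1 of 15 lower, and 5 adjusted over the list alone, with a median of -0.26 (adjusted p = 1.39e-13, and adjusted p = 0.000568 with an estimated correlation). Neuroectoderm genes had no called member of 22 over all genes by edgeR, and 8 higher and 1 lower adjusted over the list alone, with a median of 0.29 (adjusted p = 2.82e-09, but adjusted p = 0.324 with an estimated correlation). The metallothionein, cell cycle, collagens and matrix, and pluripotency lists also passed by camera, but each lost its call with 1 library left out. Without FPM_IC50 replicate 1 the adjusted p was 0.145 for cell cycle and 0.712 for collagens and matrix. It was 0.513 for pluripotency without FPM_IC50 replicate 2, and 0.294 for metallothioneins without replicate 3.

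The 2 genes called between the FPM doses over all genes were DLX1 and PRRX1, both lower, with 784 genes at unadjusted p under 0.05. DESeq2 called 40, and edgeR with the replicate number as a block called 34, 14 higher and 20 lower. The count was 1 without FPM_IC25 replicate 3, and 0 without FPM_IC50 replicate 1, replicate 2 or replicate 3. With the block, the simple epithelium list (upward, camera adjusted p = 0.0431) and the nuclear oxidative phosphorylation list (downward, camera adjusted p = 0.0135) newly passed. Both also passed with GC correction and block (camera adjusted p = 0.0155 each).

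**Figure D4:**
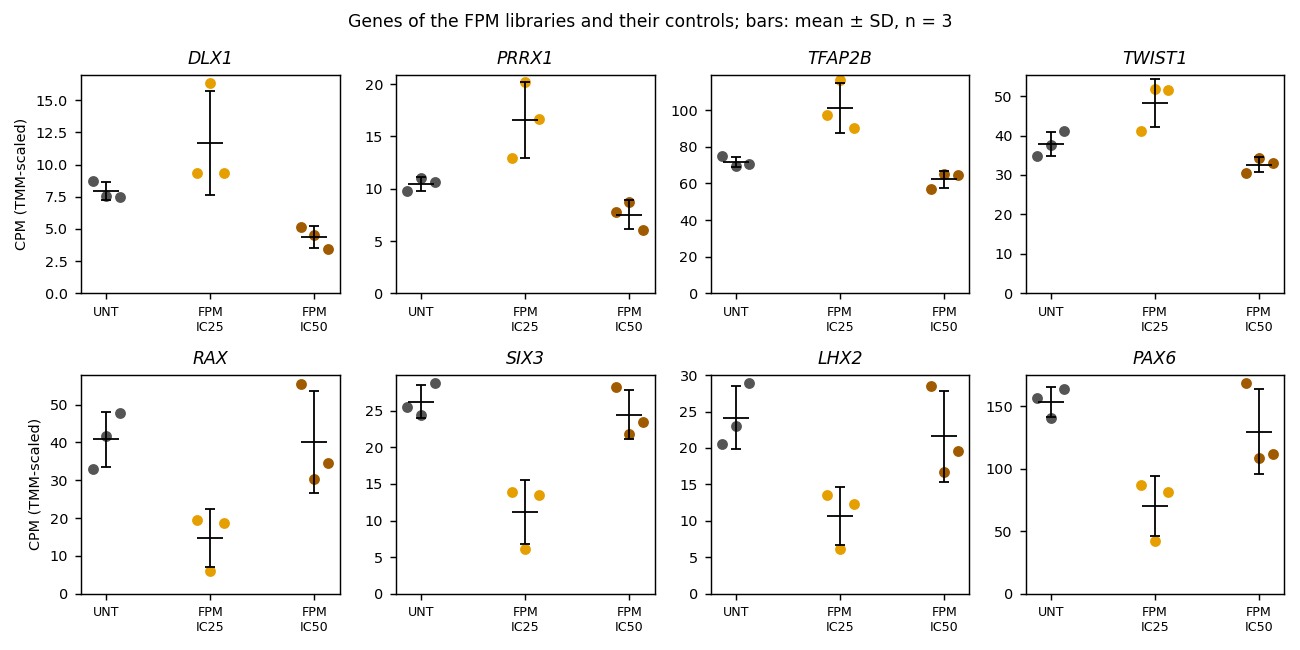
Normalised expression (CPM) of DLX1, PRRX1, TFAP2B, TWIST1, RAX, SIX3, LHX2 and PAX6 in each UNT, FPM_IC25 and FPM_IC50 library, with the mean and SD of 3 libraries; the last 6 genes were chosen after their values were seen. DLX1 lay at 11.7 ± 4.03 CPM at FPM_IC25 and 4.39 ± 0.874 at FPM_IC50, and SIX3 at 11.16 ± 4.404 and 24.48 ± 3.366.

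The particles were compared directly at the same inhibitory level, at which their concentrations differ. At IC25, ALPL was lower in FPM than in SRM by 0.39 on the log2 scale (SE 0.088, adjusted p = 0.00531), but by 0.25 (SE 0.087, adjusted p = 0.0979) after the GC correction, and the growth factor gene FGF9 (-0.86), VGLL2 (-0.82) and DLK1 (-0.79) were lower as well. The non-coding RNAs 7SK (-1.67) and SNORD3A (-1.61) had the largest differences in that direction, and PRRX1 was higher by 0.62. 7SK ranged from 25.35 to 61.85 CPM across the SRM_IC25 libraries. How the selection of polyadenylated RNA treated 7SK and SNORD3A is not known here, so their values are uncertain. Log2 fold change and GC content had a Spearman correlation of -0.38 across genes, which are not independent replicates, in this comparison. After the GC correction SNORD3A in FPM_IC25_vs_SRM_IC25 (adjusted p = 0.0584) no longer passed, while FGF9, VGLL2, DLK1, 7SK and PRRX1 did. The neuroectoderm list had 2 of 22 members lower, and 9 adjusted over the list alone, with a median of -0.35 (adjusted p = 0.00332, but adjusted p = 0.757 with an estimated correlation). Ribosomal protein genes had 1 of 34 lower, also adjusted over the list alone, with a median of -0.39 (adjusted p = 0.000375, but adjusted p = 0.757 with an estimated correlation). In all, 1880 genes were higher and 115 lower in FPM, and 92.6% of the higher genes overlap opposite exons, the 5 with the largest rises (PP2D1, LHFPL5, CFAP126, PMCH and SH2D7) included. Of these calls, 19 higher and 43 lower were genes with no opposite-strand gene within 5 kb. Fitted alone, edgeR called 0 of those genes (460 at unadjusted p under 0.05). Of 30 named genes, 14 kept their call with each library left out in turn.

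At IC50, amnion and trophoblast genes were higher and pluripotency genes lower in FPM than in SRM. The amnion and trophoblast list had 20 of 21 members higher and 1 lower in FPM, also adjusted over the list alone, with a median of 2.86 (adjusted p = 2.53e-25, but adjusted p = 0.0726 with an estimated correlation). CGA was higher by 6.53, CYP19A1 by 5.65 and the keratin gene KRT7 by 2.95. Exons of CYP19A1 and KRT7 overlap exons of an opposite gene, so their values are uncertain in a comparison with FPM libraries. The pluripotency list had 15 of 21 lower and 1 higher, also adjusted over the list alone, with a median of -1.30 (adjusted p = 4.73e-12, and adjusted p = 0.00299 with an estimated correlation). NANOG differed by -1.94 (SE 0.17, adjusted p = 1.65e-07), PRDM14 by -3.60, HES3 by -3.85, LCK by -3.42, SNCB by -3.41 and the WNT inhibitor WIF1 by -3.37. FGF and ERK targets had 13 of 22 lower, also adjusted over the list alone (adjusted p = 3.07e-05, and adjusted p = 0.0235 with an estimated correlation), but did not pass over genes with no opposite-strand gene within 5 kb (adjusted p = 0.206). Lateral plate and cardiac mesoderm genes (adjusted p = 0.0671) and collagens and matrix genes (adjusted p = 0.0990) did not pass over all genes, and passed with that restriction (adjusted p = 0.0301 and 0.00453). Cell cycle genes had 28 of 35 lower, also adjusted over the list alone, with a median of -0.35 (adjusted p = 1.31e-05, but adjusted p = 0.155 with an estimated correlation). ALPL was lower by 1.09 and CYP1A1 by 0.95 in FPM. In all, 4402 genes were higher and 3074 lower, and 63.6% of the higher genes overlap opposite exons. Tested alone, genes with no opposite-strand gene within 5 kb were higher in 705 cases and lower in 756.

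**Figure D5:**
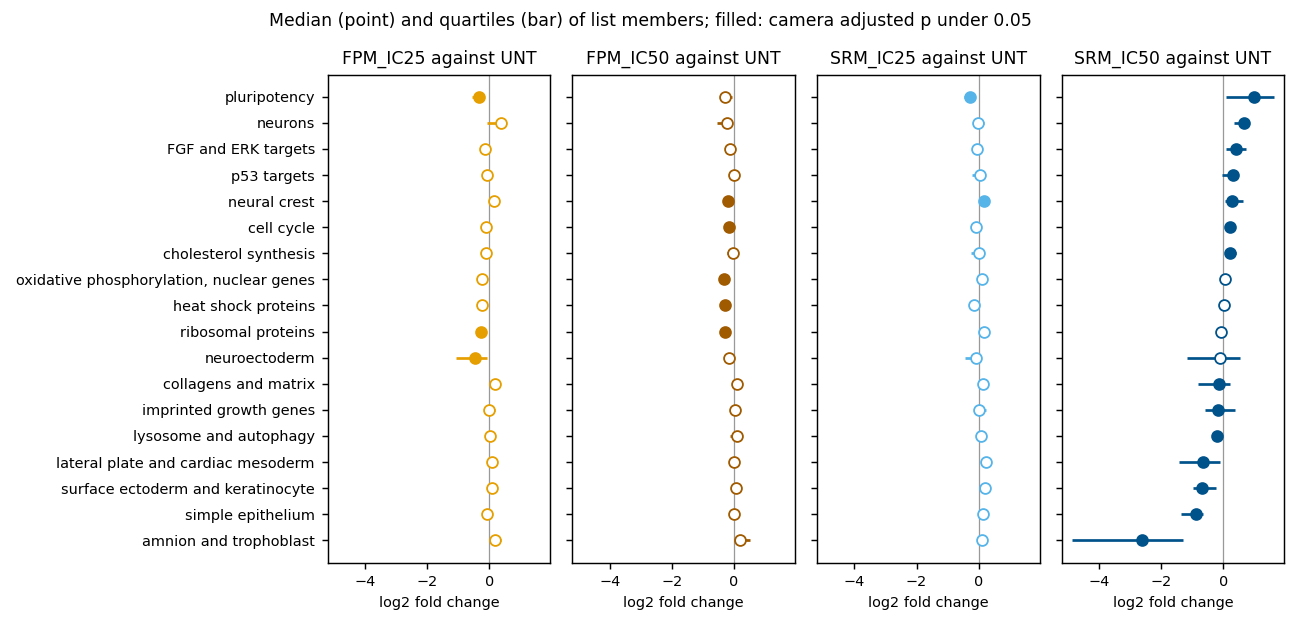
Median (point) and quartiles (bar) of the log2 fold changes against UNT of the members of 18 gene lists in each exposure; filled points mark lists with a camera adjusted p under 0.05. At SRM_IC50 the median was -2.61 for amnion and trophoblast genes and 1.00 for pluripotency genes.

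The number of genes differing among the 5 groups by the F test was 7758 of 19012, and 1493 over genes with no opposite-strand gene within 5 kb. The exposures share their controls, so similarity was set against 10 simulations of unchanged groups with the same controls. Over genes with no opposite-strand gene within 5 kb, log2 fold changes of FPM_IC25 and FPM_IC50 correlated across genes, which are not independent replicates, with r = 0.698 against 0.499 simulated. Their covariance was 0.108 against 0.0371. FPM_IC25 and SRM_IC25 had r = 0.579 against 0.547 and a covariance of 0.0714 against 0.0375. FPM_IC50 and SRM_IC50 had r = -0.0712 against 0.477, and a covariance of -0.0207 against 0.0361. SRM_IC25 and SRM_IC50 had r = 0.0697, with a covariance of 0.0161 against 0.0367; over all genes their covariance was 0.113, against 0.0720 to 0.0846 in the simulations, and r = 0.278 against 0.553. Because 3 controls cannot be divided, part of any excess over the simulations can come from the controls.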

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

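All tests of explanations in this part, the counts over other splits included, were chosen after the results were seen. The direct contrasts between particles were planned.

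The direct contrast between the particles was planned as the test of whether their effects differ, since both share the controls, and picked out these results. The share of counts in antisense genes was 1.07% and 1.21% in the FPM groups, and 0.2998% and 0.303% in the SRM groups. An effect of the particle and this difference between libraries cannot be told apart for genes that the latter can reach. At IC25, 1995 genes differed between FPM and SRM, and 92.6% of the higher genes overlap opposite exons. Of the 4239 genes with no opposite-strand gene within 5 kb, the fit over all genes called 19 higher and 43 lower. Fitted alone, 0 of the 4239 were called by edgeR (460 at unadjusted p under 0.05). The count therefore cannot be read as a difference in effect. ALPL was lower in FPM on the log2 scale (-0.39, SE 0.088, adjusted p = 0.00531). After the GC correction the ALPL difference was -0.25 (SE 0.087, adjusted p = 0.0979), so its call ended because the fold shrank. At IC50, 7476 genes differed, and 63.6% of the higher genes overlap opposite exons. Fitted alone, 1461 of the 4239 genes with no opposite-strand gene within 5 kb were called. The count of 7476 is therefore no measure of a difference in effect alone. Among the exposure markers, CYP1A1 (-0.95), CYP1B1 (-0.70) and NQO1 (-0.47) were lower in FPM_IC50 than in SRM_IC50, and HMOX1 was higher (0.38, adjusted p = 0.0477). Among the bone markers, SP7 (-0.95), ALPL (-1.09), COL1A1 (-0.51) and SPP1 (-0.64) were lower and RUNX2 was higher (0.67). The pluripotency factors POU5F1 (-1.80), NANOG (-1.94) and SOX2 (-1.48) were lower too, so the lower ALPL need not reflect the bone lineage. Exons of CYP1B1 and POU5F1 overlap exons of an opposite gene, so their values are uncertain. No group of 3 was tested for single libraries far from the others.

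Genes that lie opposite another gene were higher in both FPM groups. If reads had lost their strand of origin, each such gene would gain what its opposite gene yields. This was measured over 1061 genes with a prediction of at least 2 CPM and a UNT level under 10% of it. The median gain was 0.446 of that prediction at FPM_IC25 and 0.532 at FPM_IC50, against 0.00383 at SRM_IC25. The choice of genes used UNT alone, so the difference between FPM and SRM does not follow from it. A loss of strand in the FPM libraries could give such a gain. Antisense transcription induced by FPM would also raise antisense genes that share no exon with an opposite gene, but over 137 of them the median log2 fold change was -0.036 at FPM_IC25 and -0.00035 at FPM_IC50, against 3.90 and 4.12 over 1626 that share exons. The filter can admit genes through the FPM libraries alone, which inflates the latter medians. Unfiltered genes of any type under 0.1 CPM in UNT, inside an opposite gene without shared exons, gained 13.78 CPM per megabase of exon at FPM_IC25. The gain was 2.289 at SRM_IC25, and 423.4 at FPM_IC25 where exons are shared. A smaller rise without shared exons is thus not excluded. DNA in the FPM libraries would raise genes with no opposite gene too, but their gain per kilobase was 0.857% and 0.860% of that of genes over opposite exons. The pattern covers all libraries of 1 particle and no others, so what made them differ from the rest stays open.

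At SRM_IC25 the called genes followed GC content. After the GC correction 0 of 831 calls were left: the median size of their log2 fold changes went from 0.40 (median SE 0.0918) to 0.17 (median SE 0.0865), and 98.4% of 824 kept their direction, so the calls ended because the folds shrank. A GC bias between libraries may thus account for most of the size of these changes. A response shared with the higher dose stays open, as the values point both ways. Of the 831 genes, 61.9% (514) moved the same way at SRM_IC50, fewer than the 89.9% to 92.2% in simulated groups without a change that share the controls. The covariance of the fold changes over all genes (0.113) was above the simulated 0.0720 to 0.0846, but r (0.278) was below the simulated 0.510 to 0.573. Over genes with no opposite-strand gene within 5 kb the covariance was 0.0161, below the simulated 0.0342 to 0.0418. The pluripotency list, which fell, still passed after the correction (adjusted p = 1.055e-11; list: pluripotency, SRM_IC25_vs_UNT), though not over genes with no opposite-strand gene within 5 kb (adjusted p = 0.101). Without the correction it also did not pass with an estimated correlation (adjusted p = 0.273). Against the same 3 controls the median of this list was -0.26 at SRM_IC25, -0.32 at FPM_IC25 and -0.30 at FPM_IC50. At FPM_IC50 the list did not pass (camera adjusted p = 0.0603), and at SRM_IC50 its median was 1.00. High values in the shared controls could give such falls, and cannot be told apart here from a response. Whether part of what is left is a response to SRM at this dose stays open.

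At SRM_IC50, pluripotency genes were higher and amnion and trophoblast genes lower. GC bias is argued against as the whole cause, as 3395 genes were called after the correction and the list medians were 0.999 and -2.60, against 1.00 and -2.61 before. Scaling between libraries is argued against too as the whole cause: it moves all genes of a library alike, but the lower quartile of the pluripotency list lay above the upper quartile of the amnion and trophoblast list by 1.36 in log2 fold change. A change in the mix of cells, such as fewer amnion-like or trophoblast-like cells, was not tested against a change within cells, and both stay open.

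For each comparison of 3 libraries with 3, the 10 splits of the 6 libraries are too few for a share under 0.05. Counts with the 6 libraries alone were 2238 for FPM_IC25 against UNT, 1931 for FPM_IC50 against UNT, 2329 for SRM_IC50 against UNT, 3956 between the SRM doses, 1919 between the particles at IC25 and 5768 between them at IC50, and the highest of the other splits was 0 in each. The real split gave 0 for SRM_IC25 against UNT and for FPM_IC50 against FPM_IC25, as did all 10 splits; 4 of the latter part all 3 numbered pairs. For genes differing among the 5 groups, 1 of 60 divisions, the real one with 7758 genes, gave as many, and the highest of the others gave 1. A division that mixes FPM with other libraries widens the spread within groups, so low counts there were to be foreseen. The count shows only that the libraries are not interchangeable. It cannot exclude a difference between cultures or batches.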

How the results depend on the processing

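The restriction to genes with no opposite-strand gene within 5 kb, the GC correction and the fit of the 9 UNT and SRM libraries were added after seeing the data; all other tests here were planned. Of 11075 values of named genes under alternatives, 9802 kept direction and side of the threshold, 1234 no longer passed, 18 newly passed and 21 changed direction. Of 676 values of the 57 list tests that passed, 568 kept both, 107 no longer passed and 1 changed direction. Among the other list tests, 14 newly passed with the restriction, 10 with the GC correction, 56 with no filter and 6 with the replicate block. The cause of each change below was not tested, except that the restriction tests 4239 genes in place of 19012, and that leaving out a library or a group leaves fewer samples; where a group keeps 2 libraries, the fit pools the spread of all groups.

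Counts with the restriction, and in brackets with the GC correction as well, were as follows. For genes changed: FPM_IC25 vs UNT, it was 30 (16). For genes changed: FPM_IC50 vs UNT, it was 3 (2). For genes changed: SRM_IC25 vs UNT, it was 95 (0). For genes changed: SRM_IC50 vs UNT, it was 1058 (1068). For genes changed: SRM_IC50 vs SRM_IC25, it was 1378 (1259). For genes changed: FPM_IC25 vs SRM_IC25, it was 0 (0) with edgeR. For genes changed: FPM_IC50 vs SRM_IC50, it was 1461 (1500). The number of genes differing among the 5 groups was 1493 with the restriction. With the replicate block, the count for FPM_IC25 against UNT was 4079; the block moved no other count by over 1.5 times except those for SRM_IC25 against UNT and between the FPM doses.

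The count for SRM_IC25 against UNT (genes changed: SRM_IC25 vs UNT) was 1976 with DESeq2, 2718 with the replicate block, 0 with the 6 libraries compared (3653 at unadjusted p under 0.05), 0 with the 9 UNT and SRM libraries (3616) and 0 with the GC correction (1304), all 3 with edgeR. It ranged from 0 to 793 with 1 library left out. Between the FPM doses (genes changed: FPM_IC50 vs FPM_IC25) it was 40 with DESeq2, 116 with no filter, 34 with the block, 8 with the restriction, 24 with restriction and block and 37 with GC correction and block. It was 0 with limma-trend on log2(FPKM + 1) (738 at unadjusted p under 0.05), 0 on log2(FPKM + 0.1) (577) and 0 with edgeR on the 6 libraries compared (695), and 0 to 2 with 1 library left out.

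Of 352 gene list tests, 57 passed; 14 did with an estimated correlation, 112 with no filter and 37 with the restriction. The neural crest list at SRM_IC50 against UNT changed direction with the restriction (adjusted p = 0.82; list: neural crest, SRM_IC50_vs_UNT). Some lists had fewer than 4 members under the restriction, which cannot give a value for them; simple epithelium, surface ectoderm and lysosome are 3 of these.

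Markers that changed direction had not passed in any of these comparisons. SP7 at FPM_IC25 (main log2 fold change -0.02) was 0.0036 with DESeq2, 0.041 with the block, 0.021 with the restriction and -0.21 to 0.21 with 1 library left out. SP7 at FPM_IC50 was 0.010 with the restriction and -0.25 to 0.33 with 1 left out. HMOX1 at SRM_IC25 was -0.047 with the GC correction and -0.036 with both, and ALPL at SRM_IC25 -0.18 and -0.17. With 1 library left out, HMOX1 went from -0.043 to 0.19 at FPM_IC25 and from -0.17 to 0.019 at SRM_IC50. At FPM_IC50, COL1A1 went from -0.062 to 0.22, RUNX2 from -0.039 to 0.33 and CYP1B1 from -0.23 to 0.10. At SRM_IC25, CYP1A1 went from -0.32 to 0.047 and ALPL from -0.011 to 0.090.

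Smaller changes are missed more often: on simulated data for SRM_IC25 against UNT, 20% of genes with a log2 change of 0.5 in size were recovered, 73.8% at 1 and 89.7% at 2. In a simulated GC bias, 441 genes were called without the correction (121 truly changed) and 120 with it (114 truly changed).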

Other observations

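The chromosome test below was chosen after the result was seen. Several gene groups moved at SRM_IC50 against UNT beyond those described. Cell cycle genes had 8 of 35 members higher, and 17 adjusted over the list alone, with a median log2 fold change of 0.21 (adjusted p = 0.000749, but adjusted p = 0.189 with an estimated correlation); CDC6, a replication licensing factor, rose by 0.41. Cholesterol synthesis genes had 7 of 23 higher and 1 lower, and 10 higher and 1 lower adjusted over the list alone, with a median of 0.20 (adjusted p = 0.00210, but adjusted p = 0.185 with an estimated correlation). Lysosome and autophagy genes had 6 of 23 lower, with a median of -0.19 (adjusted p = 0.00241, but adjusted p = 0.350 with an estimated correlation); TFEB, a regulator of lysosomal genes, was -1.93 and the protease gene CTSL -1.44. p53 targets had 7 of 20 higher, and 7 higher and 1 lower adjusted over the list alone (adjusted p = 0.0190, but adjusted p = 0.557 with an estimated correlation), with DDB2, a DNA damage sensor, at 0.72 and the nuclease gene AEN at 0.69. Over genes with no opposite-strand gene within 5 kb, the cell cycle (adjusted p = 0.102), cholesterol synthesis (adjusted p = 0.785) and p53 (adjusted p = 0.172) lists did not pass, and the lysosome list had too few members to test. The p53 list did not pass without UNT replicate 1 (adjusted p = 0.102) or SRM_IC50 replicate 3 (adjusted p = 0.0861).

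Surface ectoderm genes had 4 of 7 lower at SRM_IC50, and 5 adjusted over the list alone, with a median of -0.69 (adjusted p = 0.00305, but adjusted p = 0.157 with an estimated correlation). Neural crest genes had 10 of 22 higher and 4 lower, and 11 higher and 4 lower adjusted over the list alone (adjusted p = 0.0190, but adjusted p = 0.501 with an estimated correlation). Exons of 6 of the 10 overlap exons of an opposite gene, and over the 7 members with no opposite-strand gene within 5 kb the test pointed down (adjusted p = 0.820). FOXD3, an early neural crest factor, rose by 1.07 and TFAP2A fell by 0.67. Neuron genes had 6 of 18 higher and 2 lower, and 9 higher and 2 lower adjusted over the list alone, with a median of 0.66 (adjusted p = 0.0214, but adjusted p = 0.355 with an estimated correlation); they did not pass without UNT replicate 3 (adjusted p = 0.0589) or over genes with no opposite-strand gene within 5 kb (adjusted p = 0.124). Among vitamin D response genes, TRPV6 (-1.99), VDR (-1.37), the receptor, and CYP24A1 (-0.92) were lower, with 3 of 7 lower and 4 lower and 1 higher adjusted over the list alone (adjusted p = 0.0809). At FPM_IC50 against UNT, nuclear genes of oxidative phosphorylation had no called member of 29 by edgeR (adjusted p = 0.0330, but adjusted p = 0.866 with an estimated correlation). That list did not pass without UNT replicate 3 (adjusted p = 0.203) or FPM_IC50 replicate 2 (adjusted p = 0.178), nor over genes with no opposite-strand gene within 5 kb (adjusted p = 0.148).

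A change in the number of copies of a chromosome region, which cultured stem cells can acquire, was tested as a hypothesis for SRM_IC50 against UNT. Over 152 windows of 20 to 40 neighbouring genes, on autosomes only, the largest median log2 fold change was 0.171 in size, below the 0.322 that 1 extra copy in 0.5 of the cells would give. The largest was 0.212 at FPM_IC25, 0.204 at FPM_IC50 and 0.273 at SRM_IC25. Changes that spare most of a window, lie outside the autosomes or are carried by fewer cells stay open.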
